A study of Homo sapiens with 6 samples.

How the data were processed

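The series measured circular RNAs (circRNAs, covalently closed transcripts made by back-splicing) in HCT116 cells, an established human colorectal carcinoma line, here in a form labelled drug resistant. The drug is not given in the sources used here. RNA came from 2 places, the cells themselves (cellular RNA) and the exosomes they released (exosomal RNA), with 3 replicates of each that the series design calls independently grown and harvested. Per the labels, cells grew in RPMI medium with 10% fetal bovine serum and 5% carbon dioxide, cellular RNA was isolated with an RNeasy kit, and exosomal RNA with an exoEasy Maxi kit. RNA source and isolation kit therefore changed together. Per the labels' protocols, total RNA was treated with RNase R, an exonuclease that degrades linear RNA, then amplified and labelled with Cy3 by random priming, and hybridised to a 1-colour Arraystar circRNA array with 1 sample per array.

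The scanner files hold intensity values per spot, made with Agilent Feature Extraction 11.0.1.1 per the file headers. The processed intensity in them had the background subtracted and a spatial trend removed, with no scaling between arrays. The table of the whole series, as deposited, holds values read here, by their range, as log2 values for 13084 of the 13617 circRNA probes. The submitters' processing notes name limma without its role, and the method behind that table is not given in the sources used here. Within each array the order of the table's values was the order of the median spot signal minus the median local background (Spearman correlation 1 on every array). Its 6 columns had medians of 5.66, 5.66, 5.68, 5.71, 5.70 and 5.72 for exosomal replicates 1 to 3 and cellular replicates 1 to 3. The direction of its values therefore follows the scanner signal, while their exact scale, the centring step and the filter stay unknown. None of the 533 circRNA probes missing from it was well above background on more than 2 arrays. The table served as an alternative only, and 0 of its columns were left unused.

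Each array carried 15603 spots, of which 15067 were not scanner controls. These made up 13762 probes, namely 13617 circRNA probes, 70 probes for linear messenger RNAs (mRNAs) with 10 spots each, 60 negative probes of the array maker and 15 circRNA control probes. The circRNA probes carry only the maker's probe IDs, and the sources used here do not pair those with circRNA names, types, positions or host genes. For that reason 2 probe IDs are printed per direction and the others are summarised. The 70 mRNA probes carry RefSeq accessions, all 70 of which were matched, without versions, to current gene symbols in a RefSeq gene table of assembly GRCh38.p14, used for names only. Of them 20 are custom probes of the array maker and 50 are from Agilent's catalogue. The comparison of mRNA probes was chosen after the data were examined. So was setting each of them against the 100 tested circRNA probes nearest in mean cellular signal.

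Spots called outliers by the scanner software were left out, saturated spots would have been kept (there were 0), and spots of a probe were averaged on the log2 scale. The main values are log2 processed signal minus the array's 75th percentile over all 13762 non-control probes. A probe was tested if it was well above background, in the scanner software's own call, on all 3 arrays of at least 1 group. A probe with 10 spots counted as detected where at least 50% of its spots were. Groups were compared with limma 3.58.1 (lmFit and eBayes with the default prior) in R 4.3.3, with Benjamini-Hochberg adjustment over the probes tested, separately for circRNA and mRNA probes. A probe changed if its adjusted p was under 0.05. Every log2 fold change is exosomal minus cellular. Values per array were compared with an exact two-sided permutation test of the group means, whose smallest p is 0.1 for 3 against 3 arrays. For a probe not well above background on any array of a group, the fold is a bound. It sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. Gene lists with at least 5 tested probes were compared with the other mRNA probes by camera with a preset correlation of 0.01, and again with an estimated one.

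The test, the samples, the gene lists named as fixed and the rule for named probes were set before the data were examined. The rule takes the 12 highest and 12 lowest probes by fold among those with adjusted p under 0.05, a fold of at least 2, detection on all 6 arrays and groups that did not overlap, the 6 brightest probes, the 5 largest bounds per direction, and the 2 members of each described list with the smallest adjusted p per direction. It was written for circRNA probes and was carried over to the mRNA probes. Planned tests of circRNA types, of host gene lists, of circRNA length and of a panel of known circRNAs were not run, because they need names or positions of the probes. Of the 15 lists fixed as host genes, 6 have at least 1 member among the mRNA probes and are reported there as mRNA, not as host genes. The lists were DNA damage response and repair (5 tested), cell cycle and mitosis (2), mesenchymal, fibroblast and extracellular matrix (2), chromatin modifiers and remodellers (1), WNT and beta-catenin signalling (1), and liver and plasma protein (1). Another 5 lists were added after the data were examined, namely ribosome and translation (6), cytoskeleton (6), blood cell genes (5), DNA replication and cell division (14), and genes best known from other tissues (11).

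The alternatives for scaling were quantile, median, cyclic loess and no scaling, and a percentile over probes detected on all 6 arrays. Further ones were normexp background correction with an offset of 50, other filters on dim probes, a replicate block and the deposited table. Stricter thresholds were tried too, and each array was left out in turn. A robust fit was also run, with an intensity trend for circRNA probes and without one for mRNA probes. The files have no mean spot signal, so normexp used the median spot and background signals. Without scaling and with normexp, the fit gave every named mRNA probe the same SE (0.59 and 0.28). The named circRNA probes also shared 1 SE (0.53) without scaling. Passing in those fits depends on the fold alone and not on the spread of a probe's own replicates. A random scan block and a filter on the 95th percentile of the negative probes were added after the data were examined. The cellular arrays shared 1 scan, exosomal replicates 1 and 3 shared another, and exosomal replicate 2 had one of its own, so no scan held both groups. The number of arrays limits the precision. On simulated data with 12636 circRNA probes and the real spread, the test recovered 3% of 100 probes changed by 1 on the log2 scale and 50% of 100 changed by 2, with 1 false call among 54. With 68 mRNA probes it recovered 70% of 10 probes changed by 1 and 80% of 10 changed by 2, with 2 false calls among 17. Only 200 circRNA and 20 mRNA probes were changed there, against 9737 and 58 called in the real data. The adjusted threshold was therefore stricter in the simulation, and these shares do not give the power of the real test. Figures were drawn with matplotlib 3.10.9.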

Results

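RNA from exosomes, the small vesicles that cells release, was compared with RNA of the drug-resistant HCT116 cells that released them, on 3 arrays each. On exosomal replicates 1, 2 and 3, 10994, 12277 and 11751 of the 13617 circRNA probes were well above background. On cellular replicates 1, 2 and 3 the numbers were 12418, 12112 and 12218. The means, 11674 ± 645 and 12249 ± 155 (SD, n = 3 each), gave an exact two-sided permutation p of 0.3, where 0.1 is the smallest that 3 against 3 arrays allow. The difference depended on the detection call. It was −575 probes with this call, 95.3 with the scanner's weaker call, and −3224 with the 95th percentile of the negative probes as the limit (8558 against 11781 probes, exact two-sided permutation p = 0.1). With 1 array left out it ran from −877 (without exosomal replicate 2) to −235 (without exosomal replicate 1). The median circRNA signal was 13.9, 23.8 and 17.5 on the exosomal arrays and 86.3, 44.3 and 79.1 on the cellular arrays (exact two-sided permutation p = 0.1). The 70 linear mRNA probes went the other way relative to the circRNA probes of their array. Their median lay 0.39 ± 0.11 above the circRNA median on the exosomal arrays and at −2.17 ± 0.67 relative to it on the cellular arrays (log2 scale, SD, n = 3; exact two-sided permutation p = 0.1). Rank correlations of circRNA signal across probes, which are not independent replicates, were 0.942 to 0.972 within groups and 0.323 to 0.560 between groups.

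**Figure D1:**
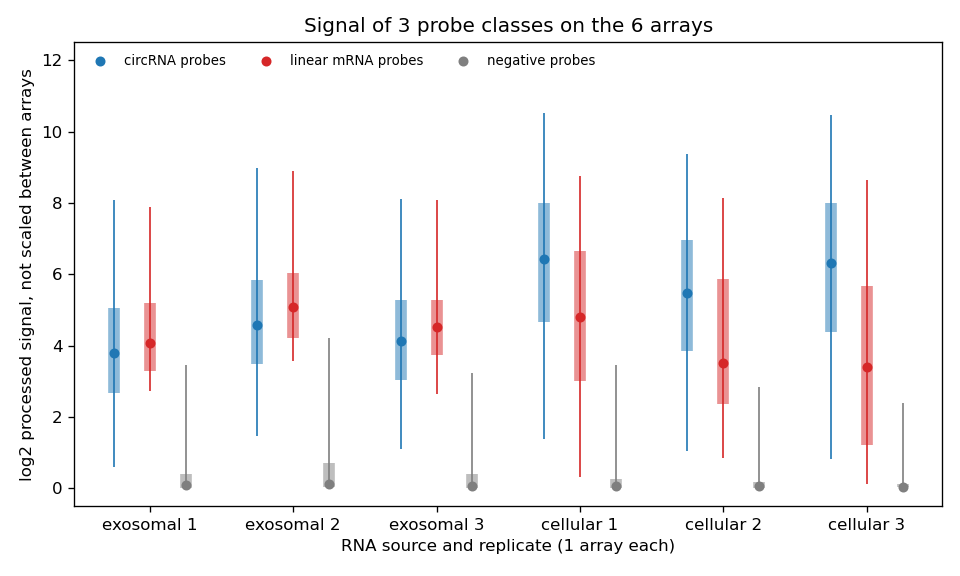
Distribution of log2 processed signal (vertical axis, not scaled between arrays) for circRNA, linear mRNA and negative probes on each of the 6 arrays (horizontal axis). Points are medians, thick bars run from the 25th to the 75th and thin lines from the 5th to the 95th percentile of probes; the mRNA median lies above the circRNA median on the 3 exosomal arrays and below it on the 3 cellular arrays.

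The main question of the design was which circRNAs differ between exosomes and their cells. Most probes differed between the 2 sets of arrays, which also differed in scan and isolation kit. Of 12705 circRNA probes tested, 9737 (76.6%) changed, 5829 higher and 3908 lower in exosomal RNA (limma, adjusted p under 0.05). A change of at least 2-fold was found for 8911, of which 5391 were higher and 3520 lower, and one of at least 8-fold for 2290 higher and 938 lower probes. In 10238 probes (80.6%) the 3 values of one group all lay above the 3 of the other, against 10% by chance. In the main values the probe ASCRP3004677 was the highest in exosomal RNA, with a log2 fold change of 8.74 ± 0.36 (SE, n = 3 and 3, limma adjusted p = 4.692e-06) and a mean signal of 1470 in exosomal against 16.4 in cellular RNA. ASCRP3008077 came next at 7.77 ± 1.00 (adjusted p = 6.285e-05), although its cellular replicates spread widely (SD 2.57 on the log2 scale) and leaving 1 of them out gave 6.60 to 9.14. It lay above ASCRP3004677 with normexp (6.32 against 5.85), in the deposited table (6.54 against 6.12) and without cellular replicate 2 (9.14 against 9.05). The lowest were ASCRP3004722 at −7.30 ± 0.34 (signal 63.3 against 47401) and ASCRP3007501 at −7.27 ± 0.32 (23.2 against 17030), both with adjusted p = 4.692e-06. ASCRP3007501 was the lower of the pair with quantile normalization (−7.77 against −7.59), without exosomal replicate 3 (−7.48 against −7.30) and without cellular replicate 2 (−7.11 against −6.97). The 12 highest probes had log2 fold changes of 5.57 to 8.74 and the 12 lowest −7.30 to −5.74. The 6 brightest probes had log2 fold changes of 0.51 to 1.89, of which 4 passed (limma, largest adjusted p 0.241). Without scaling all 6 were negative, at −1.74 to −0.36.

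The split between higher and lower depended on the level in the cells. The 9757 probes well above background on all 6 arrays were ranked by cellular signal and divided into 5 equal groups. The dimmest group (median signal 17.9 in cells and 19.8 in exosomes) had a median log2 fold change of 2.56, with 1856 of 1952 probes higher and 0 lower. Medians then fell through 1.19, 0.32 and −0.70 to −1.99 in the brightest group (median signal 717 in cells and 40.2 in exosomes), where 373 of 1952 were higher and 1353 lower. These groups were formed from one of the values compared, which by itself tilts them in this direction. The choice of scaling sets where the line between higher and lower falls. Exosomal arrays had a 75th percentile 2.25 log2 units below the cellular arrays, and relative to the main values the median probe moved by −0.50 under quantile, −0.36 under median, −0.53 under cyclic loess and −2.25 under no scaling. Higher and lower probes then numbered 1840 and 7578 with no scaling, against 5829 and 3908. Other steps changed too in 2 further alternatives. The numbers were 7589 and 2409 with normexp, which changes the background step. They were 4620 and 4721 in the deposited table, whose processing is unknown. Of the changed probes, 5748 kept both call and direction with no scaling and 8901 with quantile normalization. Many of these signals were low, and of the 12705 tested probes 8855 (69.7%) lay below the brightest negative probe on every exosomal array, against 1529 on every cellular array. No scan held arrays of both groups, so scan and RNA source cannot be told apart.

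**Figure D2:**
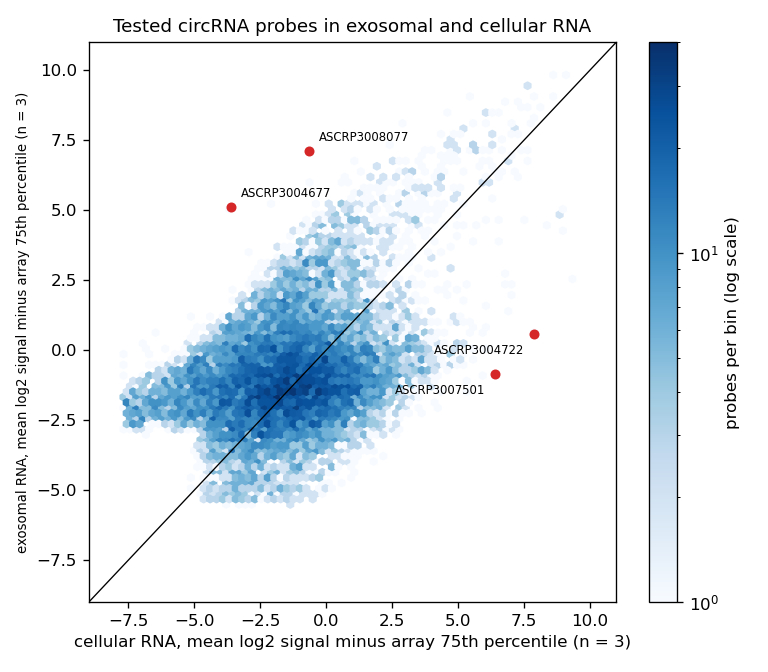
Each of the 12705 tested circRNA probes by its mean log2 signal, minus the array's 75th percentile, in cellular RNA (horizontal axis, n = 3) and in exosomal RNA (vertical axis, n = 3); the shade gives the number of probes per bin on a log scale and the line marks equal values. Red points are the 4 named probes, with log2 fold changes of 8.74, 7.77, −7.30 and −7.27.

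Some circRNA probes were detected in one RNA source only. Well above background on all 3 exosomal and on no cellular array were 404 probes, and 625 showed the opposite pattern, while 9757 were detected on all 6 arrays and 294 on none. A bound on the fold could be given for 395 of the exosomal probes, with a median of at least 12.4-fold and a highest of at least 71.8-fold. For 427 of the cellular probes the median bound was 2.38-fold and the highest 32.5-fold. These bounds hold for the scaled values. Without scaling the highest was 15.1-fold and the median 2.60-fold over 395 exosomal probes, and 155-fold and 6.92-fold over 625 cellular probes. These counts depend on the detection call. With the 95th percentile of the negative probes as the limit they were 185 exosomal and 2315 cellular, with the scanner's weaker significance call 110 and 62, and without exosomal replicate 2 the cellular count was 1015.

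The 70 linear mRNA probes gave the one comparison with named genes. The RNA had been treated with RNase R, which degrades linear RNA. These probes therefore read signal left after that treatment, and their folds need not be those of the mRNAs themselves. Of 68 tested, 55 were higher and 3 lower in exosomal RNA relative to the arrays' 75th percentile. The lower ones are housekeeping genes. ACTG1, which encodes cytoplasmic gamma actin, was 9.75-fold lower (log2 −3.29 ± 0.49, SE, limma adjusted p = 1.167e-04). RACK1, a scaffold protein of the ribosome, was 3.71-fold lower (−1.89 ± 0.43, adjusted p = 0.00185) and the glycolytic enzyme GAPDH 2.28-fold lower (−1.19 ± 0.41, adjusted p = 0.0185). All 3 were lower under every scaling tried, but the size depends on it, and without scaling they stood at log2 −5.54, −4.14 and −3.44. The GAPDH call was lost without exosomal replicate 1, 2 or 3 or cellular replicate 1, with adjusted p of 0.0888, 0.0699, 0.0597 and 0.0548. The 10 mRNA probes that did not pass had log2 fold changes of −0.62 to 1.18.

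Among mRNA probes well above background on all 6 arrays, SPDL1, which brings dynein to kinetochores, was 23.8-fold higher (log2 4.57 ± 0.54, limma adjusted p = 4.900e-05, signal 53.8 against 10.8). H3-3A, which encodes histone H3.3, was 23.4-fold higher (4.55 ± 0.62), and UCHL5, a deubiquitinase of the proteasome, 20.2-fold (4.33 ± 0.46). Their order depends on the processing, since H3-3A lay above SPDL1 with quantile (4.03 against 3.85), cyclic loess (4.69 against 3.97) and normexp (2.97 against 2.15). The next were RAD54B (3.50), the mitochondrial import protein MTX1 (3.44), ZNF195 (3.33), the GTPases RHOH (3.24) and RND3 (3.18), DNTTIP2 (3.17), ODC1, the first enzyme of polyamine synthesis (3.10), the dynein light chain DYNLL1 (3.09) and ABRAXAS1, a partner of BRCA1 (2.93), with SEs of 0.41 to 0.57 and adjusted p of at most 1.969e-04. Without scaling, SPDL1, H3-3A and UCHL5 stayed above the threshold, at log2 2.32, 2.30 and 2.08, and the other 9 stayed positive but did not pass. That fit gave these probes 1 shared SE (0.59), so passing depended on the fold alone. Without scaling 25 mRNA probes were higher and 10 lower, and 43 of the 55 kept a positive sign under every scaling tried.

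Another 7 mRNA probes were well above background on all 3 exosomal arrays and on no cellular array, and 0 showed the opposite. GRM4, a metabotropic glutamate receptor, was at least 21.1-fold higher (limma adjusted p = 8.306e-06), LOX, which cross-links collagen, at least 16.5-fold, LMO2, a transcription cofactor of blood cell precursors, at least 16.1-fold, SAA4, a serum amyloid protein, at least 15.9-fold, and CD69, an early activation marker of lymphocytes, at least 12.2-fold. PLA2G4A (at least 11.1-fold) and SPP1 (at least 9.53-fold), named after their values were seen, made up the rest. These bounds include the scaling between arrays. Without it they were 4.43-fold for GRM4, 3.47-fold for LOX, 3.38-fold for LMO2, 3.34-fold for SAA4, 2.56-fold for CD69, 2.34-fold for PLA2G4A and 2.00-fold for SPP1. With normexp, whose offset shrinks folds of dim probes, the fitted log2 fold changes were 1.59 (SPP1) to 1.84 (GRM4). Their mean signals on the exosomal arrays were low, from 8.70 for SPP1 to 19.3 for GRM4, and those on the cellular arrays were 1.09 to 2.30. All 7 lay below the highest negative probe on every exosomal array, and only 2 of them, GRM4 and LOX, exceeded the 95th percentile of the negative probes on all 3.

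By gene list, 4 of 5 DNA damage response and repair probes were higher, both among all mRNA probes tested and when adjusted over the list alone, and 2 passed as higher without scaling. BRCA1 (log2 4.93 ± 0.63, detected on 1 of 3 cellular arrays) and the helicase WRN (3.85 ± 0.51, detected on 2 of 3) had the smallest adjusted p, followed by RAD54B. With normexp, whose offset shrinks folds of dim probes, BRCA1 stood at 1.82 and WRN at 1.72. The exonuclease gene EXO1 stood at 1.29 ± 0.51 (adjusted p = 0.0352). It was lost without exosomal replicate 1, 2 or 3 (adjusted p = 0.123, 0.0699 and 0.0910), with median centring (0.93, adjusted p = 0.0864) and with the replicate block (adjusted p = 0.0530), and turned negative without scaling (−0.96). SMC6 did not pass (1.18 ± 0.59, adjusted p = 0.0832), but did without cellular replicate 1 (adjusted p = 0.0164), with normexp (1.12, adjusted p = 1.236e-04), over probes detected on all 6 arrays (adjusted p = 0.0492) and with a random scan block (adjusted p = 0.00132). Without scaling it was −1.07. The list did not differ from the other mRNA probes (camera p = 0.836, and p = 0.924 with an estimated correlation). Both probes of the cell cycle and mitosis list were higher. CENPE, a kinetochore motor, stood at 4.86 ± 0.64 (detected on 1 of 3 cellular arrays), or 1.88 with normexp. CCNA2, cyclin A2, stood at 2.79 ± 0.73 and did not pass without scaling (0.54, limma adjusted p = 0.429). Of the mesenchymal list LOX and LOXL2 (3.79 ± 0.58, detected on 2 of 3 cellular arrays, or 1.72 with normexp) were higher. BAZ1A, the single member of the chromatin list, was higher (4.20 ± 0.48, detected on 1 of 3 cellular arrays), or 1.68 with normexp. CPS1, the urea cycle enzyme of the liver list, was higher too (2.25 ± 0.47, but −0.0057 without scaling). TCF7, the single member of the WNT list, did not pass (0.70 ± 0.41). TCF7 passed as lower without scaling (−1.55, adjusted p = 0.0188), and as higher with normexp (1.04, adjusted p = 3.055e-04) and with a random scan block (0.68, adjusted p = 0.00611), and it was −0.21 with quantile and −0.31 with cyclic loess scaling. No scan held both groups, so the random scan block cannot take a scan difference out of the SMC6 and TCF7 comparisons.

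Among the lists added later, 11 of 11 genes best known from other tissues were higher. Of the 11, 2 (CFTR and CPS1) are also made by intestinal epithelium, and 3 were well above background on all cellular arrays. Without scaling 8 passed as higher and 3 were below 0. Their median log2 fold change was 4.77, or 3.99 with undetected probes at their bound, but the list did not stand apart from the other mRNA probes (camera adjusted p = 0.353, and adjusted p = 0.924 with an estimated correlation). Of 14 DNA replication and cell division genes 12 were higher and 2 did not pass. DTL, a substrate receptor of a ubiquitin ligase, stood at 5.63 ± 0.60 (detected on 1 of 3 cellular arrays), or 2.07 with normexp. Without scaling 6 of the 14 passed as higher and 1 as lower. Of 5 blood cell genes 4 were higher, CD69 and LMO2 among them, and 1 did not pass, while without scaling 2 passed as higher and 1, TCF7, as lower. The 6 ribosome and translation genes divided into 5 higher, among them RPL10 (3.88 ± 0.47, detected on 1 of 3 cellular arrays) and EIF3D (1.77 ± 0.40), and RACK1, which was lower. Without scaling 4 of those 5 were below 0, with 1 gene passing as higher and 1 as lower. With normexp RPL10 stood at 1.60. Of 6 cytoskeleton genes 4 were higher, RND3 and DYNLL1 among them, ACTG1 was lower and 1 did not pass. Without scaling 0 passed as higher and 1 as lower. ACTB, beta actin, named after its values were seen, was 3.57-fold higher (1.83 ± 0.42) where ACTG1 fell. Without scaling ACTB stood at −0.42 and EIF3D at −0.48. Camera gave these 4 lists adjusted p of 0.812, 0.736, 0.494 and 0.494, and 0.924 each with an estimated correlation. The ribosome and cytoskeleton lists had medians of 1.54 and 2.34, above 0 but below those of the other mRNA probes (3.09 and 3.01). For the replication list the median, 2.85, lay below that of the others while the test pointed upward. As a whole the 68 mRNA probes lay above the circRNA probes (median log2 fold change 2.92 against 0.50, camera adjusted p = 1.042e-06), which was lost with an estimated correlation (adjusted p = 0.549, correlation 0.579). The 48 catalogue probes had a median of 3.29 (camera adjusted p = 2.520e-07, and 0.549 with an estimated correlation) and the 20 custom probes one of 1.77 (camera p = 0.110). Each of these sets was compared with the other tested probes, circRNA and mRNA alike. The 2 sets were not tested against each other. The gap of 2.41 was 0.78 with normexp and 1.30 over probes detected on all 6 arrays. It was 0.69 when each mRNA probe was set against the 100 tested circRNA probes nearest to it in cellular signal. Of 68 mRNA probes, 50 lay above their neighbours' median. Actin, GAPDH, histone and ribosomal genes have many near-identical copies in the genome, so their probes may also read those copies.

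**Figure D3:**
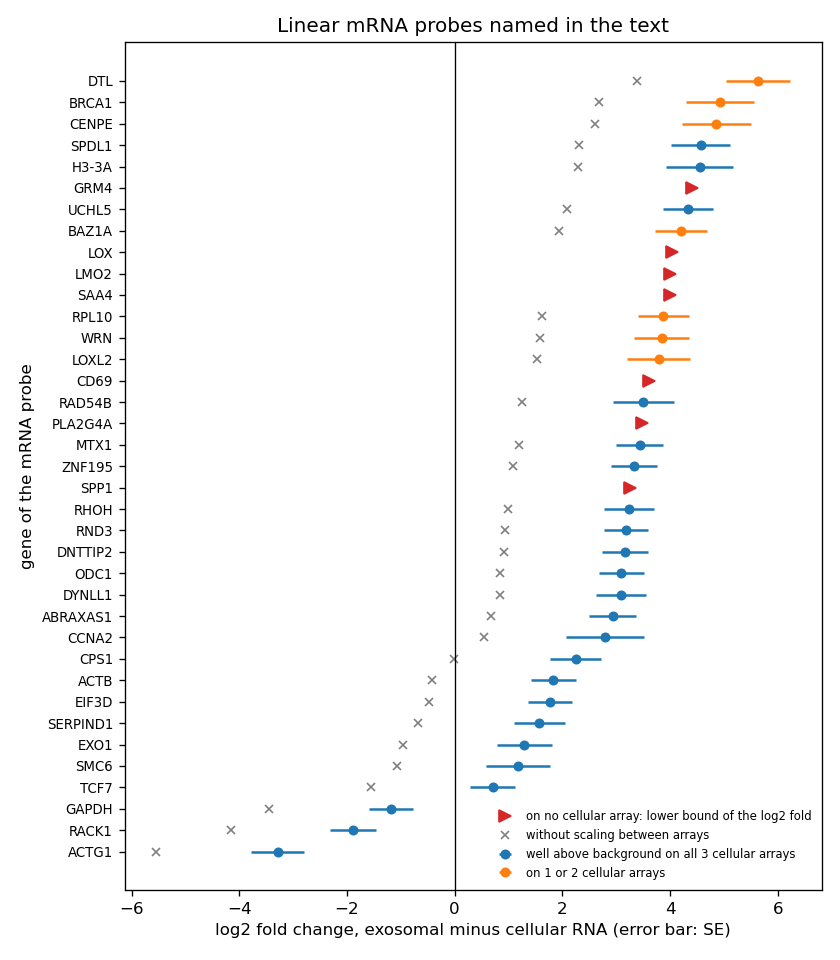
Log2 fold change, exosomal minus cellular RNA (horizontal axis), of the mRNA probes of the named genes (vertical axis), 3 arrays per group. Circles with SE bars are colored by the number of cellular arrays with the probe well above background, triangles are lower bounds for the 7 probes detected on none, and crosses are the values without scaling; ACTG1, RACK1 and GAPDH lie below 0 with and without scaling, and EXO1, SMC6, EIF3D, ACTB, SERPIND1, CPS1 and TCF7 change sign without it.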

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

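The tests in this part were chosen after the values they bear on were seen, except the counts over other splits of the samples. The rule for those splits was set before, but the mRNA comparison it was also applied to was chosen after the data were examined. Some probes outside the comparisons were brighter in exosomal RNA. Of the array maker's 60 negative probes, 17 had all 3 exosomal signals above all 3 cellular signals, where chance gives 5%, and 4 had them all below. The median signal of the 17 was 1.77 against 1.11. Of the 60 control sequences of the scanner design, 26 had all 3 exosomal signals above all 3 cellular ones and 5 had them below, and the median gain over all 60 was 0.12 on the unscaled log2 scale. The 26 had a median signal of 11.4 against 5.12 and gained a median of 0.94 and at most 2.38, with 12 of them gaining at least 1. The 15 circRNA control probes went the other way, with 1 above, 11 below and a median change of −4.25.

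Linear mRNA probes stood higher relative to circRNA probes in exosomal RNA, and the tables argue against light added equally to all probes as the whole cause. Equal light would keep the order of the 2 medians. The mRNA median lay at −1.64, −1.94 and −2.92 (log2) from the circRNA median on the cellular arrays, but 0.28, 0.50 and 0.40 above it on the exosomal ones. The negative probes' gain in signal before background subtraction (75th percentile 1.05, 4.47 and 0.59 on exosomal replicates 1, 2 and 3) was also taken off every probe. The mRNA median then lay 2.58 above the circRNA median (quartiles 1.25 and 4.09 over mRNA probes), against 2.41 before. This subtraction decides nothing, because an equal loss lowers the dimmer circRNA median of the exosomal arrays more. Dimness in cells stays open as a cause, since the median excess over circRNA probes of like cellular signal was 0.69 (quartiles −0.036 and 1.41 over probes). How much it explains cannot be told, because the neighbours were tested probes. A circRNA probe not detected on every cellular array was among them only if detected on all 3 exosomal arrays. This can raise the neighbours' folds and lower the excess. The same filter kept 68 of 70 mRNA probes and 12705 of 13617 circRNA probes. Template that does not depend on which genes the cells express, such as DNA, less complete RNase R digestion, binding of particular off-target sequences, the different isolation kits, and a true difference between vesicles and cells stay open and untested.

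The second pattern is that circRNA probes dim in cells were higher and bright ones lower in exosomal RNA. The probes were ranked by one of the values compared, which by itself tilts the folds in this direction. How much of the pattern comes from that was not tested. A compressed signal range alone would keep the order of probes, but the highest rank correlation between an exosomal and a cellular array was 0.560, below the lowest of 0.942 within a group. Signal near the floor stays open, because 69.7% of the tested probes lay below the highest negative probe on all 3 exosomal arrays. Of those, 3065 were higher and 3405 lower. A difference between scans cannot be told apart from RNA source, because 0 of the 3 scans held both groups. A difference in circRNA content between exosomes and cells stays open too. For both counts, 1 of the 10 splits of the 6 samples, the real one, gave as many changed probes. The real split gave 9737 circRNA and 58 mRNA probes and the highest of the others 0 for each. Every other split put arrays of both sources in each group, so a difference between sources became spread within groups. Their 0 calls therefore say little, and 10 splits are too few for a share under 0.05.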

How the results depend on the processing

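A random scan block and the limit from the negative probes were chosen after the data were examined, as were the alternatives for the count of changed mRNA probes and for the mRNA median. The other alternatives for single named probes were fixed before. The count of changed circRNA probes stayed within 1.5 times its main value under every alternative run, as did the count changed at least 2-fold. Leaving out 1 array in turn gave 9045 to 9645 changed circRNA probes, 8700 to 9040 changed at least 2-fold, a share of higher probes of 59.9% to 61.0%, 53 to 60 changed mRNA probes, an mRNA median of 2.13 to 2.68 above that of circRNA probes, a difference in detected probes per array of −877 to −235, and 407 to 496 exosomal and 628 to 1015 cellular probes detected in one source only. The share of higher probes, 59.9% in the main values, was 50.7% with quantile, 53.1% with median, 49.9% with cyclic loess and 19.5% with no scaling, 58.7% with the percentile over probes detected on all 6 arrays, 75.9% with normexp, 62.7% with no filter, 63.6% over probes detected on all 6 arrays, 49.5% in the deposited table and 56.1% above the negative probes. Under another scaling the median probe moved, by −0.50 with quantile, −0.36 with median, −0.53 with cyclic loess and −2.25 with no scaling. It moved by −0.065 with the percentile over probes detected on all 6 arrays. Such shifts move the line between higher and lower. Why the share differed under the other alternatives was not tested. The count of changed mRNA probes, 58, fell to 35 with no scaling and to 37 over probes detected on all 6 arrays, where fewer (44) were tested. The mRNA median above the circRNA median, 2.41, was 1.97 with cyclic loess, 0.78 with normexp and 1.30 over probes detected on all 6 arrays. The difference in detected probes per array, −575, turned to 95.3 with the scanner's weaker call. Probes detected in one source only, 404 exosomal and 625 cellular, became 110 and 62 with that call and 185 and 2315 above the negative probes. Without scaling EXO1 (−0.96), SMC6 (−1.07), EIF3D (−0.48), ACTB (−0.42), SERPIND1 (−0.68), CPS1 (−0.0057) and TCF7 (−1.55) turned negative, as did SMC6 (−0.019) and TCF7 (−0.31) with cyclic loess and TCF7 (−0.21) with quantile normalization. Same-numbered replicates correlated at 2.875e-04, 0.135 and 0.188 in their deviations across probes. Exosomal replicates 2 and 3 correlated best with the cellular replicate of their own number, and exosomal replicate 1 with cellular replicate 2 (0.139). With 3 replicates per group, these values cannot decide whether the numbers pair the samples. The replicate block gave 9748 circRNA and 57 mRNA probes, and EXO1 then had an adjusted p of 0.0530. The random scan block gave 10826 circRNA and 66 mRNA probes. Each scan lay within 1 RNA source, so this block cannot remove a scan difference, and its added calls are no further evidence of change. A fixed scan or slide block was not run because no scan held both groups, and alternatives for circRNA types, host gene lists, length and the circRNA panel were not run because the probes have no names here. Low signal limits the exosomal arrays most, where 62.8% of circRNA probes exceeded the 95th percentile of the negative probes, against 86.5% on the cellular arrays.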

Other observations

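The counts and medians in this part were chosen after the data were examined. The 15 circRNA control probes of the array maker had median signals of 20.5, 47.3 and 36.4 on exosomal replicates 1, 2 and 3 and of 493, 332 and 669 on the cellular ones, and 11 of them had all 3 exosomal signals below all 3 cellular signals.

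The cellular replicates spread more than the exosomal ones in catalogue mRNA, custom mRNA and circRNA probes. The median SD between replicates of the catalogue probes was 0.96 in cellular and 0.22 in exosomal RNA on the log2 scale. It was 0.49 and 0.19 for custom mRNA probes, and 0.41 and 0.28 for circRNA probes. Relative to the array's 75th percentile the catalogue probes had medians of −3.87, −3.98 and −5.30 on cellular replicates 1, 2 and 3 and of −1.07, −0.99 and −0.95 on the exosomal ones. The liver gene SERPIND1 was among the brighter mRNA probes in both sources (mean signal 173 in exosomal and 278 in cellular RNA), and its log2 fold change was 1.57 ± 0.48 (SE, limma adjusted p = 0.0101), or −0.68 without scaling.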
